A study of Mus musculus with 8 samples.

How the data were processed

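Bulk RNA sequencing measured gene expression in brain tissue of 8 male mice of 3 months of age, 4 wild type (WT) and 4 carrying the label Nsun5-KO. Per the labels' protocols, 5 mice of each genotype from the same litter were used and the animals were anaesthetised with pentobarbital at 50 mg/kg; 4 libraries per genotype were analysed here. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit, which does not mark the strand of a transcript, so reads from genes that overlap on opposite strands cannot be told apart. Reads were aligned with HISAT2 2.0.5 to the mouse build mm10, per the submitters' processing notes. The read counter and its annotation are not given in the sources used here.

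The deposited counts are whole numbers of reads per gene that had not been normalised, for 54532 genes, with gene coordinates, length and biotype per the file headers. The deposited FPKM values (fragments scaled by gene length and library size) equal those counts divided by gene length and by a single constant per library, which was 0.9813 to 1.022 times the library total. A deposited column of mean FPKM per group equals the mean of the 4 libraries and was not used here. Gene symbols were taken from the deposited table; 103 symbols occur more than once there, and for those the gene identifier with the highest mean count was used in gene lists.

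Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group, which left 16062 genes, of which 14174 were protein-coding. Libraries were scaled with the trimmed mean of M values, and genotype was tested with the robust quasi-likelihood F test, without covariates, over all 8 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05 with no fold minimum. Fold changes are log2 values of the libraries labelled Nsun5-KO over WT. CPM, the count scaled to the library size, is given as mean ± SD over 4 libraries. Per-gene tests of CPM at 4 against 4 used an exact two-sided permutation over 70 labelings, whose smallest p is 0.0286.

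Gene lists were fixed before the data were examined: 36 lists of cell type, regional and pathway genes, plus sex-linked genes as a check of the samples. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The self-contained test fry was run on the same values, and its p asks whether the genes of a list move, on balance, in a single direction; its mixed p asks whether they change in either direction. List p-values were adjusted over the 35 lists tested; the pituitary list had 2 tested members and was left out. Counts of list members were made over all genes and adjusted over the list alone. A score per library was the mean log2 CPM of the tested members minus its WT mean.

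The genes named in the text follow a rule fixed before the data were examined. It takes Nsun5, a fixed set of myelin genes (Mbp, Mog, Mag, Mobp and Cnp among them), up to 12 called genes per direction with a mean CPM of at least 1 and separate groups, the 3 members of each list with the smallest p, and the 10 genes with the smallest p if fewer than 5 genes are called. Some genes that the rule takes are not reported here. Other genes named below were chosen after their values were seen and are marked as such.

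Alternatives were DESeq2 1.42.0, limma voom with sample weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other scalings and low-count filters, protein-coding genes alone, a surrogate variable from sva 3.50.0, the replicate number as a block, and each library left out in turn. Transcript GC content came from GENCODE M21 transcripts. After the result was seen, the ribosomal protein genes were also compared with 1354 other genes, drawn as the 20 nearest to each member in length and GC content. The pipeline was tested on simulated counts for this comparison, with 15850 genes tested and 200 simulated as changed, besides 2 shifted lists of 40 genes. All of these were drawn from genes with an average log2 CPM above 1, so the recovery does not cover sparser genes. The pipeline recovered 6% of genes changed 1.25-fold, 50% of those changed 1.5-fold, 76% of those changed 2-fold and 94% of those changed 4-fold, and 8.8% of its calls were unchanged genes. In the same simulation camera called 2 of 2 lists shifted by -0.4 (log2) and 0 of 20 unchanged lists. Its genes were drawn independently of each other, while the real myelin list had an estimated correlation of 0.484. The simulation therefore does not show how often camera calls unchanged lists of correlated genes.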

Results

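Gene expression in brain tissue was compared between mice labelled Nsun5-KO and WT littermates. The design text names the whole brain, but the cerebellar granule cell gene Gabra6 had 0 to 30 counts and the Purkinje cell gene Pcp2 0 to 19 in the 8 libraries. Other members of the cerebellar list, which other brain regions express too, had more, such as Calb1 with 2568 to 3921. Gabra6 and Pcp2 were chosen after their values were seen, and the counts leave open which part of the brain was taken. Nsun5 encodes an RNA methyltransferase that places 5-methylcytosine on the large ribosomal RNA, and the series asks about myelin and sleep in mice that lack it. The 8 libraries held 15642086 to 17829523 counts each, and 22210 to 22944 genes had at least 1 count. Mitochondrially encoded genes took 5.52% to 7.68% of counts. No pair of libraries within a group agreed within sampling noise, since the chi-square per degree of freedom lay between 7.74 and 22.3. The first principal component held 25.7% of the variance and set WT replicates 1 and 2 (29.7 and 36.0) apart from the other 6 libraries (-23.8 to -1.7).

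Nsun5 RNA was not lower in the libraries labelled Nsun5-KO. Nsun5 (ENSMUSG00000000916, chromosome 5, 135369953 to 135376805, mm10) had 91, 82, 103 and 109 counts in WT replicates 1 to 4 and 102, 124, 83 and 110 counts in the libraries labelled Nsun5-KO. The mean was 5.74 ± 0.538 CPM in WT and 6.28 ± 0.887 CPM in the libraries labelled Nsun5-KO (SD, n = 4 each; log2 fold change 0.13, SE 0.15, 95% interval -0.20 to 0.47, edgeR adjusted p = 0.817; exact permutation p = 0.314). The 3' end of Nsun5 overlaps Pom121 on the opposite strand (135376141 to 135394546), which had up to 1369 counts in a library, and reads in the shared part cannot be assigned to either gene. The gene-level count therefore did not separate the genotypes, and every direction below is that of the libraries labelled Nsun5-KO, whose labels this gene did not bear out.

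The myelin genes lay lower in the libraries labelled Nsun5-KO, with 39 of 40 tested members below WT and a median log2 fold change of -0.40. Mbp, which encodes myelin basic protein, had 3010 ± 205 CPM in WT and 2285 ± 372 CPM in the libraries labelled Nsun5-KO (log2 fold change -0.40, SE 0.11). Mobp, another myelin protein, had 1037 ± 27.1 and 778.7 ± 106 CPM (log2 fold change -0.41). Anln (-0.51), Mal (-0.46), Cnp (-0.40) and Mog (-0.39) lay lower as well. The myelin-associated glycoprotein gene Mag was at -0.28, with a 95% interval of -0.63 to 0.06. Without replicate 3 labelled Nsun5-KO, Mog was at -0.26 and Mag at -0.19, and Mag was at -0.18 without WT replicate 3. EdgeR called no myelin gene over all genes (adjusted p = 0.313 for Mbp, 0.307 for Mobp), and 28 of the 40 were lower when adjusted over the list alone. As a group the list was called lower by camera (adjusted p = 9.47e-20), but the adjusted p = 0.30 with an estimated correlation and 0.092 with fry, whose test of change in either direction gave 0.035. The exact permutation p of the library scores was 0.0286, the smallest this design can give. In the same libraries the score of thalamic and midbrain genes was -0.84, 0.26, -0.78 and -0.03 for replicates 1 to 4 labelled Nsun5-KO, and the myelin score was -0.50, -0.13, -0.62 and -0.25. Without replicates 1 and 3 labelled Nsun5-KO, a choice made after seeing the data, the myelin median was -0.21.

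**Figure D1:**
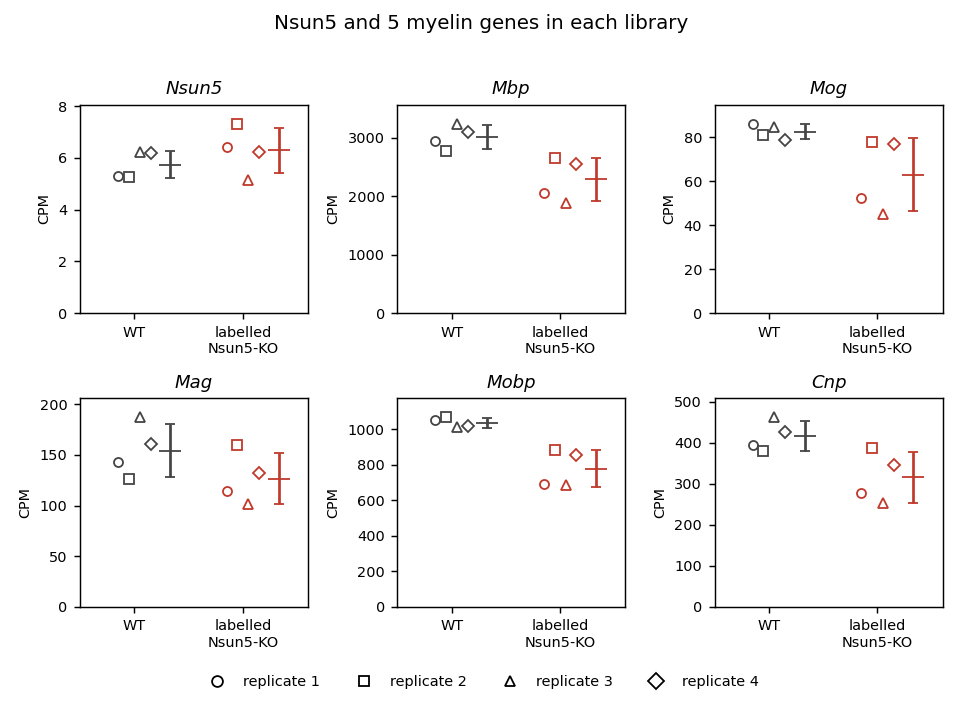
CPM (vertical axes, from 0) of Nsun5 and 5 myelin genes in each library, by group, with a marker per replicate and a bar for the mean ± SD of 4 libraries. Nsun5 was not lower in the libraries labelled Nsun5-KO (5.74 and 6.28 CPM), while Mbp had 3010 and 2285 CPM and replicates 1 and 3 labelled Nsun5-KO were lowest for Mbp.

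Genes of earlier oligodendrocyte stages lay closer to WT. The precursor list had a median log2 fold change of -0.08 and was called lower by camera (adjusted p = 0.035), with an adjusted p = 0.53 with an estimated correlation. Sox10, the transcription factor of the lineage, was its only member lower when adjusted over the list alone (log2 fold change -0.48, SE 0.12; edgeR adjusted p = 0.313 over all genes). C1ql1 was at -0.50 and Lims2 at -0.32. The newly formed oligodendrocyte list had a median of -0.15 and was called lower (camera adjusted p = 0.00996), with an adjusted p = 0.49 with an estimated correlation and 0 members passing when adjusted over the list alone. Neu4 was at -0.45, Sirt2 at -0.19 and Kif19a at -0.58. Leaving out WT replicate 1, 2 or 4, or replicate 1 or 3 labelled Nsun5-KO, ended the call of the precursor list (median -0.10, -0.064, -0.10, -0.056 and -0.081), and leaving out WT replicate 3 or replicate 1 labelled Nsun5-KO ended that of the newly formed list (-0.078 and -0.098).

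The number of genes called depended on the test. The edgeR test gave 0 of 16062 genes at an adjusted p below 0.05 (smallest adjusted p = 0.178), with 852 higher and 811 lower at an unadjusted p below 0.05 (803 expected by chance). DESeq2 called 94 genes (52 higher, 42 lower), among them 5 lower myelin genes, 4 lower hypothalamic genes and 3 higher clock genes. With single libraries left out, a choice made after seeing the data, DESeq2 called 43, 20, 251 and 170 genes without WT replicate 1, 2, 3 or 4 and 37, 65, 39 and 157 without replicate 1, 2, 3 or 4 labelled Nsun5-KO. Of the 94 genes, 18 to 79 were called again. EdgeR without the low-count filter called 68, of which 52 were shared with DESeq2. Limma with voom weights and limma on log2(FPKM + 1) called 0. The groups did not overlap in 916 genes, or 5.70%, where chance gives 2.86% on average. Genes are not independent, and this share was not compared with other groupings of the 8 libraries, so chance was not excluded for it. The 10 genes with the smallest edgeR p, which edgeR with the low-count filter did not call and DESeq2 and edgeR without it did, included Pak7, a kinase of the PAK family, at 51.5 ± 4.09 CPM in WT and 84.4 ± 12.1 CPM in the libraries labelled Nsun5-KO (log2 fold change 0.71, SE 0.11, edgeR adjusted p = 0.178). Hecw2, a ubiquitin ligase, was at 0.63, Kcnh7, a potassium channel, at 0.60 and Drp2 at 0.37. Tac2, the neurokinin B precursor gene, was at -1.03 (SE 0.15, adjusted p = 0.178), Efnb3 at -0.62 and Tppp3 at -0.64. Hdc, the histamine-synthesising enzyme of hypothalamic neurons, was at -2.17 and the ciliary dynein gene Dnah6 at -1.40. Eif3j2 was at -1.50, but it is a near-identical copy of Eif3j1 and its count is uncertain. Without replicate 4 labelled Nsun5-KO, edgeR called 2 genes, Pak7 among them (log2 fold change 0.81, adjusted p = 0.00566).

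Genes of the hypothalamus and the ventricles lay lower in the libraries labelled Nsun5-KO. All 15 tested hypothalamic genes were below WT, with a median log2 fold change of -1.24. Nkx2-1, a transcription factor of the ventral hypothalamus, was at -1.81 (SE 0.41), Gpr50 at -1.92 and Ecel1 at -1.21. All 15 tested genes of the ependyma, the ciliated lining of the ventricles, were below WT with a median of -0.95. Dnah6 was at -1.40, Ccdc153 at -1.70 and Rarres2 at -0.69. All 18 choroid plexus genes were below WT in the group comparison, with a median of -0.91, but replicate 1 labelled Nsun5-KO lay above the WT mean (score 0.46). Prlr was at -1.31, Clic6 at -1.07 (-1.79 without replicate 1 labelled Nsun5-KO) and Trpm3 at -0.34. EdgeR called no member of the 3 lists over all genes, DESeq2 called 4 hypothalamic and 2 ependymal genes, and 5 hypothalamic, 9 ependymal and 0 choroid plexus genes were lower when adjusted over the list alone. Camera called all 3 lists lower (adjusted p = 1.28e-08, 5.03e-12 and 4.77e-06), with an adjusted p = 0.30, 0.30 and 0.58 with an estimated correlation. Libraries of a group differed widely in these genes: the hypothalamic score was 0.39, 0.65, -0.22 and -0.82 in WT replicates 1 to 4 and -1.54 to -1.10 in the libraries labelled Nsun5-KO. The hypothalamic median was -1.93 without WT replicate 3, -1.97 without WT replicate 4 and -0.61 without WT replicates 1 and 2. The choroid plexus median was -1.83 without replicate 1 and -0.55 without replicate 4 labelled Nsun5-KO, and -0.38 without WT replicates 1 and 2.

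**Figure D2:**
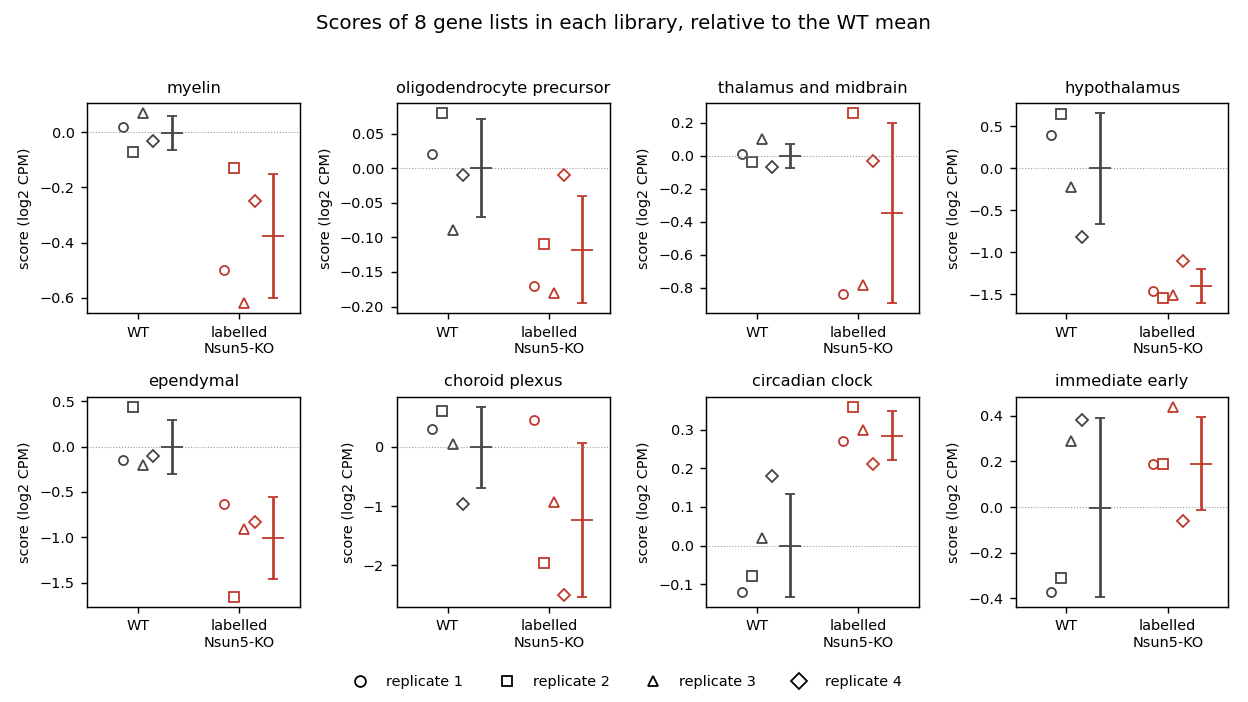
Scores of 8 gene lists (mean log2 CPM of the members minus the WT mean, vertical axes, each with its own range) in each library by group, with a marker per replicate and a bar for the mean ± SD of 4 libraries. Every library labelled Nsun5-KO had a hypothalamic score between -1.54 and -1.10, and its replicates 1 and 3 had the lowest myelin scores (-0.50 and -0.62) and thalamic and midbrain scores (-0.84 and -0.78).

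Other regions showed a mixed picture. Cortical and hippocampal genes had a median of 0.19, with Cux2 (0.56) and Tbr1 (0.48), transcription factors of cortical projection neurons, among 5 members higher when adjusted over the list alone. Camera called the list higher (adjusted p = 0.0119), with an adjusted p = 0.62 with an estimated correlation. Its call ended without WT replicate 4 (0.16) or replicate 3 labelled Nsun5-KO (0.083), its median was 0.28 without WT replicate 1, and it turned to -0.033 without replicates 1 and 3 labelled Nsun5-KO. Olfactory bulb genes had a median of -0.23 (camera adjusted p = 0.035, called lower; adjusted p = 0.30 with an estimated correlation) and 0 members passed when adjusted over the list alone. The list members Omp (1 to 6 counts) and Tbx21 (0 to 5), chosen after their values were seen, were too sparse to be tested. The olfactory bulb list is thus a weak measure of bulb tissue in these libraries. Sp8 was at -1.33 and Th, the dopamine-synthesis enzyme, at -2.01, while Shisa3 was at 0.91. Th, which midbrain neurons express too, was at 35.99 CPM in WT replicate 1 and at -0.95 without it. That call ended without WT replicate 2 or 4, or replicate 2 or 3 labelled Nsun5-KO (-0.29, -0.24, -0.33 and -0.26), and the median was -0.42 without replicate 1 and -0.38 without replicate 4 labelled Nsun5-KO. The lists of the thalamus and midbrain (median -0.045, mean -0.26, camera adjusted p = 0.343), the striatum (-0.23, 0.343) and the cerebellum (-0.076, 0.552) were not called, and 0 of their members passed when adjusted over the list alone. Striatal members Isl1 (-1.21), Tac1 (-0.44) and Gpr6 (-0.53), the cerebellar members Zic1 (-1.18), Zic2 (-0.62) and Calb1 (-0.30) and the thalamic member Cbln2 (0.37) were among those with the smallest p in their lists. The thalamic list was called lower without replicate 2 labelled Nsun5-KO (-0.54), and the striatal list was called lower without WT replicate 1 (-0.53) or replicate 4 labelled Nsun5-KO (-0.58).

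Circadian clock genes lay higher in the libraries labelled Nsun5-KO, with 21 of 23 above WT and a median log2 fold change of 0.28. Bhlhe40, a repressor in the clock feedback loop, had 108 ± 22.9 CPM in WT and 171 ± 19.4 CPM in the libraries labelled Nsun5-KO (log2 fold change 0.67, SE 0.14, edgeR adjusted p = 0.307). Hlf (0.47) and Nr1d2 (0.33), clock-controlled transcription factors, lay higher too, and 9 members were higher when adjusted over the list alone, against 0 over all genes by edgeR and 3 by DESeq2. Camera called the list higher (adjusted p = 1.35e-08), with an adjusted p = 0.30 with an estimated correlation, and its median was 0.18 without WT replicates 1 and 2. Genes of the axon and the node of Ranvier had a median of 0.14 with 22 of 24 above WT. The sodium channel genes Scn8a (0.33) and Scn1a (0.50) and the potassium channel gene Kcna2 (0.34) were among 4 higher when adjusted over the list alone. That list was called higher (camera adjusted p = 1.34e-05), with an adjusted p = 0.30 with an estimated correlation.

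Genes linked to sleep and waking moved in both directions. Hdc was lower (-2.17) and Kcna2 higher (0.34) when adjusted over the list alone, and the muscarinic receptor gene Chrm1 was at 0.26. Hdc, a gene of hypothalamic neurons, lay lower in the libraries in which all 15 hypothalamic genes did (median -1.24), and its 8.08 and 4.94 CPM in WT replicates 1 and 2 were the highest, as was the hypothalamic score. The median was 0.16 and the mean -0.009, and camera called the list higher (adjusted p = 0.035), with an adjusted p = 0.30 with an estimated correlation. That call covers 25 of 30 members, since the low-count filter removed the others, among them Hcrt, Pmch and Gal. DESeq2 called 0 members higher and 2 lower, Hdc and Gal (-2.21, DESeq2 adjusted p = 0.038). Hcrt, Pmch and Gal were chosen after their values were seen. Leaving out any single library ended the camera call (median 0.038 to 0.15). Immediate early genes had a median of 0.16, with Homer1 at 0.40, Per1 at 0.41 and Dusp6 at 0.24 and 0 members passing when adjusted over the list alone (camera adjusted p = 0.00893, called higher; adjusted p = 0.70 with an estimated correlation). The score of that list was -0.37 and -0.31 in WT replicates 1 and 2 against 0.29 and 0.38 in WT replicates 3 and 4, and the median turned to -0.072 without WT replicates 1 and 2. Its call ended without WT replicate 1 (0.062) or 2 (0.053) or replicate 3 labelled Nsun5-KO (0.077), and the median was 0.28 without WT replicate 3 and 0.26 without WT replicate 4. Homer1 and Per1 were each at 0.256 without WT replicate 1, and Dusp6 was at 0.152 without WT replicate 2. Excitatory synapse genes had a median of 0.08, with Slc17a7, the cortical vesicular glutamate transporter, at 0.31 and 0 members passing when adjusted over the list alone (camera adjusted p = 0.0159, called higher; adjusted p = 0.62 with an estimated correlation). That call ended without WT replicate 1 (0.080) or 4 (0.093) or replicate 3 labelled Nsun5-KO (0.079), the median was 0.15 without WT replicate 3 and 0.13 without replicate 2 labelled Nsun5-KO, and it turned to -0.016 without replicates 1 and 3 labelled Nsun5-KO. Inhibitory neuron genes were not called (median -0.049, camera adjusted p = 0.501). The neuropeptide genes Sst and Cort were at -0.35 and -0.49 and Gabrb2 was at 0.22.

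Among genes of the translation machinery, cytosolic ribosomal protein genes lay slightly lower, with 64 of 79 below WT and a median log2 fold change of -0.11. Rpl10 was at -0.34, Rps6 at -0.29 and Rpl17 at -0.42, and 0 members passed when adjusted over the list alone. Many of these genes have processed pseudogenes, so their counts are uncertain. Camera called the list lower (adjusted p = 1.26e-05), with an adjusted p = 0.62 with an estimated correlation, and the median was -0.066 without replicate 3 labelled Nsun5-KO and -0.056, no longer called, without its replicates 1 and 3. Lists of mitochondrial ribosomal proteins (median 0.012, mean -0.001, camera adjusted p = 0.757), ribosome biogenesis (0.024, 0.310) and translation factors (-0.014, 0.610) were not called. Their members with the smallest p were Mrpl10 (-0.23), Mrpl16 (0.25) and Mrpl51 (0.19), Polr1b (0.29), Utp4 (0.21) and Bms1 (0.19), and Eef1a1 (-0.26), Eef1b2 (-0.21) and Eef2k (0.23). For translation factors the fry test of change in either direction gave an adjusted p = 0.045. At an unadjusted edgeR p below 0.05, 5 of its members were higher and 6 lower. Genes that write or erase 5-methylcytosine were not called as a list (median -0.029, camera adjusted p = 0.531), with Nsun7 at -0.69, Trdmt1 at -0.34 and Tet3 at 0.21. Their library scores were -0.02 to 0.01 in WT and -0.13 to -0.04 in the libraries labelled Nsun5-KO. The exact permutation p of these scores was 0.0286, the smallest this design can give (adjusted p = 0.2). Tet3 was at 0.135 without WT replicate 1 and at 0.14 without replicate 3 labelled Nsun5-KO.

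All 13 mitochondrially encoded genes lay below WT, with a median of -0.20 (camera adjusted p = 0.00274, called lower; adjusted p = 0.36 with an estimated correlation). Among them mt-Nd4, a subunit of complex I, was at -0.25, mt-Co3 at -0.70 and mt-Atp8 at -1.56; 0 members passed when adjusted over the list alone, and nuclear copies make these counts uncertain. The median was -0.13 without WT replicate 2 and -0.038 without WT replicates 1 and 2. Nuclear genes of oxidative phosphorylation were not called (median 0.025, camera adjusted p = 0.378), with Sdhd at 0.20, Atp5d at 0.15 and Ndufc2 at 0.14. The list was called higher without WT replicate 4 (0.070) or replicate 3 labelled Nsun5-KO (0.059). It was called lower without WT replicates 1 and 2 (-0.074). Interferon-response genes had a median of -0.19 with Ddx58, an RNA sensor, at -0.45, Irf9 at -0.30 and Stat2 at 0.23 and 0 members passing when adjusted over the list alone (camera adjusted p = 0.0153, called lower; adjusted p = 0.65 with an estimated correlation). That call ended without WT replicate 1 (-0.17) or 3 (-0.089) or replicate 3 (-0.14) or 4 (-0.16) labelled Nsun5-KO, and the median was -0.30 without WT replicate 2.

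Genes of cholesterol synthesis, which myelin formation draws on, were not called as a list (median 0.011, mean -0.045, camera adjusted p = 0.610); Ebp was at 0.19 and the sparsely counted Fdps at -1.84. The integrated stress response (median 0.058, camera adjusted p = 0.582) and p53 target lists (median 0.059, mean -0.013, 0.451) were not called either, with Herpud1 at 0.27, Ddit4 at 0.36 and Hsp90b1 at -0.21 in the former and Zmat3 at 0.22, Perp at -0.40 and Sesn1 at 0.14 in the latter. The fry test of change in either direction gave the p53 target list an adjusted p = 0.02. Markers of astrocytes (median -0.032, camera adjusted p = 0.734), microglia (-0.056, 0.110), endothelium (0.035, 0.552), mural cells (-0.006, 0.916) and meninges (-0.12, 0.378) were not called. Camera placed the mural list higher although its median and mean (-0.027) were below 0. Sox9 was at -0.36, the microglial receptor gene P2ry12 at -0.22, Vwf at 0.36, Kcnj8 at 0.59 and Col1a1 at -0.40. Called lists appeared among these when libraries were left out: microglia lower without replicate 4 labelled Nsun5-KO (-0.14) and meninges lower without WT replicate 2 (-0.36). Blood genes were not called (median -0.013, camera adjusted p = 0.343); Hba-a2, a globin gene with a near-identical copy, was at -1.06 and was the only member lower when adjusted over the list alone, and the list was called lower without replicate 1 labelled Nsun5-KO (-0.63). Adjusted over the list alone, 0 members passed in the other lists of this paragraph.

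Genes around Nsun5 were examined because a targeted allele can carry flanking DNA of another strain. Of 229 tested genes within 10 Mb of Nsun5, 0 were called by edgeR; 21 (9.17%) had an unadjusted p below 0.05, against 10.4% of genes elsewhere (Fisher's exact test, two-sided p = 0.662). The conserved block of neighbours of Nsun5 was not called as a list (median -0.040, camera adjusted p = 0.552), with Stx1a at 0.48, Mlxipl at -0.78 and Eln at -0.46, and 0 members passing when adjusted over the list alone. The Y-linked genes Kdm5d, Uty and Eif2s3y had 23.1, 18.4 and 23.1 CPM in WT and 19.4, 20.03 and 22.7 CPM in the libraries labelled Nsun5-KO.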

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

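No test in this part was chosen after a result was seen. Within each group of 4 libraries, the gap of the highest or lowest library to its nearest neighbour was set against the whole range of the group. Of 316 groups of values examined, 25 held a library that stood apart, where chance gives about 15.8; none of these values is given an explanation.

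Replicate 4 labelled Nsun5-KO stood apart for Pak7 (66.27 CPM, others 89.98 to 91.22), Bhlhe40 (142.3, others 177.9 to 185.1), Ecel1 (18.95, others 9.886 to 11.19) and Trdmt1 (5.957, others 4.352 to 4.402), and for the sleep and wake score (0.17, others -0.04 to -0.02). Replicate 3 labelled Nsun5-KO stood apart for Bms1 (29.78 CPM, others 28.11 to 28.36), Polr1b (20.08, others 16.28 to 16.77), Tet3 (75.42, others 62.06 to 63.15), Ndufc2 (54.59, others 64.14 to 65.19) and Uty (24.06, others 18.36 to 19.13), and for the endothelial score (-0.19, others 0.07 to 0.10). Replicate 2 labelled Nsun5-KO stood apart for Calb1 (151.6 CPM, others 167.9 to 171.2) and for the p53 target score (-0.09, others 0.02 to 0.04). Replicate 1 labelled Nsun5-KO stood apart for the globin gene Hbb-bt (17.1 CPM, others 3.574 to 4.663), Nsun7 (2.075, others 3.12 to 3.295) and Sst (212.9, others 175 to 178.5), for the blood score (0.63, others -0.65 to -0.57) and for the astrocyte score (-0.12, others -0.01 to 0.01).

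Among WT libraries, replicate 1 stood apart for Th (35.99 CPM, others 5.02 to 9.811), Zic4 (2.442, others 7.681 to 8.593), Laptm5 (37.91, others 32.11 to 32.77) and Utp4 (31.92, others 27.64 to 27.74). WT replicate 2 stood apart for Slc17a7 (844.9 CPM, others 1045 to 1075), Irf9 (7.438, others 10.4 to 10.58) and the ependymal score (0.44, others -0.20 to -0.10).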

How the results depend on the processing

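The exact permutation of list scores, the removal of length and GC trends, the genes matched in length and GC, the split of all lists, the score covariates, the fits without a pair of libraries and DESeq2 with a library left out were chosen after seeing the data; the other alternatives were set before the data were examined. The cause of a change was not tested unless stated. Nsun5 stayed at 0.016 to 0.24 (log2) and was not called under the alternatives fitted for single genes, which leave out the surrogate variable, log2(FPKM + 0.1) and FPKM without a filter; the myelin median stayed negative under every alternative that tested lists, from -0.49 to -0.21. At this depth, spread and number of libraries, 6% of genes with the smallest simulated change were recovered; which of these set the limit was not tested.

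The count of called genes was 0 except with DESeq2 (94), no low-count filter (68), an unadjusted p below 0.05 (1663) and single libraries left out (0 to 2). Near Nsun5, 21 genes passed an unadjusted p. The count of called lists was 16, 0 with an estimated correlation, 0 with fry (8 in its test of change in either direction), 0 with exact permutation, 10 to 16 with single libraries left out and 9 without replicates 1 and 3 labelled Nsun5-KO; the myelin median was -0.40 in the 3 tests that ended its call (adjusted p = 0.296, 0.0916 and 0.2 by exact permutation). The exact permutation could call a list only if 21 lists were at its smallest p, and 5 were, so its 0 is no evidence against the 16. With replicate numbers as a replicate block, 0 genes and 16 lists were called, and no call depended on the block. The same-number correlations were -0.115, -0.213, -0.041 and 0.063. They gave no sign that the numbers pair the mice, but they cannot exclude it.

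Lists that changed sign, none called in the test used throughout unless stated, were: with library size only, cholesterol synthesis (-0.014), mitochondrial ribosomal protein (-0.012) and ribosome biogenesis (-0.002); with upper quartile scaling, cholesterol synthesis (-0.012) and mitochondrial ribosomal protein (-0.011); and with no low-count filter, mural (0.001). Without WT replicates 1 and 2 these were mitochondrial ribosomal protein (-0.020), immediate early (-0.072, called before), stress response (-0.018), oxidative phosphorylation (-0.074), endothelial (-0.035), blood (0.037) and cerebellum (0.075). Without replicates 1 and 3 labelled Nsun5-KO these were immediate early (-0.010), excitatory synapse (-0.016) and cortex and hippocampus (-0.033), all called before, and stress response (-0.013), astrocyte (0.066), mural (0.11), striatum (0.021) and thalamus and midbrain (0.012). Genes that changed sign were Hbb-bt with the replicate block (-0.049) and without replicates 1 and 3 labelled Nsun5-KO (-0.68), Eif2s3y with voom weights (0.031) and, without WT replicates 1 and 2, Eif2s3y (0.11) and Alas2 (0.037).

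With single libraries left out, the range was -0.59 to 0.45 for Hbb-bt, -0.92 to 0.23 for Alas2, -0.12 to 0.054 for Eif2s3y and -0.014 to 0.34 for Tshb. For lists it was -0.016 to 0.040 for mitochondrial ribosomal protein, -0.019 to 0.070 for oxidative phosphorylation, -0.064 to 0.035 for astrocyte, -0.071 to 0.054 for mural, -0.36 to 0.093 for meninges, -0.54 to 0.20 for thalamus and midbrain, -0.024 to 0.047 for cholesterol synthesis, -0.63 to 0.23 for blood and -0.27 to 0.045 for cerebellum. Across all alternatives 45 gene results passed the threshold only in the alternative. That 0 gene results lost a call shows nothing, because edgeR called 0 genes in the test used throughout. Of the list results, 99 lost a call and 13 gained it.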

Other observations

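The tests of Nsun5, the thalamic and midbrain covariate, the removal of length and GC trends, the genes matched in length and GC, the split of all lists and the fits without a pair of libraries were chosen after the result was seen, as were the genes named in the next paragraph.

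The WT libraries differed from each other in transcripts of small brain nuclei. Pmch and Hcrt, neuropeptide genes of the lateral hypothalamus, had 901 and 601 counts in WT replicate 1 and 281 and 166 in WT replicate 2, against at most 17 and 14 counts in the other 6 libraries. Slc6a3, the dopamine transporter gene of midbrain neurons, had 1302 and 229 counts in the same WT libraries and at most 38 elsewhere. Avp, the vasopressin gene, had 252, 267, 701 and 10 counts in WT replicates 1 to 4 and 37, 10, 6 and 4 in the libraries labelled Nsun5-KO. Ttr, the transthyretin gene of the choroid plexus, ranged from 618 to 17427 counts, both in libraries labelled Nsun5-KO (replicates 4 and 1). The striatal receptor gene Drd1 ranged from 326 to 1705. Among cerebellar genes, Gabra6 had 0 to 30 counts and Pcp2 0 to 19, while Calb1 had 2568 to 3921 and Car8 165 to 315.

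Nsun5 counts were not lower in the libraries labelled Nsun5-KO than in WT. With the labels as given, an allele that removes most of the counted reads is argued against, because the lower 95% bound of the log2 fold change was -0.20. A smaller loss stays open, as do reads shared with Pom121. Labels swapped between the groups stay open too: the lowest library was at 0.83 times the median of the other 7, but an allele that leaves the counted RNA in place gives the same counts under right and swapped labels. Such an allele, and knockout labels on mice with an intact gene, cannot be told apart from gene-level counts (log2 fold change 0.13).

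In the group comparison, myelin genes lay lower together with hypothalamic, ependymal and choroid plexus genes. Replicate 1 labelled Nsun5-KO departed from this, with a myelin score of -0.50 and a choroid plexus score of 0.46. An equal fall of the precursor and myelin lists is argued against by their medians of -0.08 and -0.40. The precursor member Sox10 was at -0.48, however, and the member Nxph1 is also in the inhibitory neuron list. Members that other cells express too could hold the precursor median near 0. The list median therefore cannot exclude an equal fall of the lineage's cells. A smaller fall of the lineage, or of its mature cells alone, stays open too. Length and GC bias is argued against by a myelin median of -0.41 after both trends were removed. With the mean of the choroid plexus and ependymal scores in the model, the genotype coefficient was -0.57 (SE 0.13). The slope of that mean was -0.18 (SE 0.08), so less of this tissue went with higher myelin scores. Replicates 2 and 4 labelled Nsun5-KO, lowest in choroid plexus score, had the highest thalamic and midbrain scores of that group (0.26 and -0.03). The thalamic and midbrain score was not in this fit, and its slope in a separate fit was 0.4 (SE 0.05). The fit therefore cannot separate both tissues from that region. Loss of both tissues together as the whole reason stays open. Loss of ependymal tissue alone was not tested, and its score separated the groups (-1.66 to -0.63 against -0.20 to 0.44 in WT). Less hypothalamic tissue as the whole reason stays open, because the hypothalamic score separated the groups and left a coefficient of -0.37 with SE 0.24. Less thalamic and midbrain tissue may account for part of it: the coefficient went from -0.38 (SE 0.11) to -0.24 (SE 0.04), between the bounds set for either reading. A lower expression of myelin genes by genotype also stays open, and it cannot be told apart from how the tissue was taken.

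Ribosomal protein genes lay lower while longer transcripts lay slightly higher (Spearman rho of log2 fold change with gene length 0.0676 across genes, which are not independent replicates). A length trend shared by every library labelled Nsun5-KO and by no WT library is argued against, because the lowest Nsun5-KO slope lay 0.033 below the highest WT slope (difference -0.033 log2 per doubling of length). Length and GC bias as the whole reason for the lower ribosomal protein genes stays open by the bound first written. Removal of both trends brought rho with length from 0.0676 to 0.0123 across genes. The list was still called with a median of -0.096 against -0.11 before, just short of that bound. Only a bound added later argues against such bias: 1354 other genes of like length and GC content lay nearer to 0, with a median of -0.016 (spread 0.004). That spread treats genes of the same 8 libraries as independent. Replicate 3 labelled Nsun5-KO had both the highest length slope (0.0421) and the lowest ribosomal protein score (-0.24). What lowered the list stays open, and no biological explanation was tested.

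Each split of the 8 libraries into 4 and 4 was tested in the same way as the real one, 35 splits in all. For genes called, the real count of 0 leaves nothing to test, since 35 of 35 splits gave as many; the highest other gave 4. For genes at an unadjusted p below 0.05, 3 of 35 splits gave as many as the real 1663, so chance was not excluded; the highest other, 2163, set WT replicates 1 and 2 with replicates 3 and 4 labelled Nsun5-KO. The real split alone gave 16 called lists (1 of 35, highest other 15), so chance was excluded at 0.05 for this count taken alone, by a margin of a single list. With an estimated correlation or fry, 0 lists were called. For 8 lists, most of which were those with the smallest camera p under the real labels, the splits were compared on the scale of -log10 p. The real split was highest for the ependymal list (1 of 35, 12.5 against 9.41), the hypothalamic list (1 of 35, 8.96 against 7.60) and the clock list (1 of 35, 8.81 against 7.79). Taken singly each of these shares, 0.0286, lies below 0.05, but it is the smallest these splits can give, and adjusted over the 35 lists it could pass only if 21 lists reached it. When all 35 lists were split, the real split was highest for 3, and 2 of the 35 splits, the real one included, were highest for as many, so chance was not excluded for that count. Chance was not excluded for the myelin list (2 of 35, 20.57 against 20.62), the axon and node list (2 of 35, 5.57 against 6.58), choroid plexus (10 of 35, 6.17 against 29.6), ribosomal protein (8 of 35, 5.67 against 15.1) or immediate early genes (15 of 35, 2.64 against 17.2). Several other splits called 10 or more lists, and why was not tested.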
